A study of Mus musculus with 21 samples.

How the data were processed

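Chromatin immunoprecipitation and sequencing was run on 21 samples of mouse J1 embryonic stem cells in 12 groups, and 8 groups had a list of peaks that was used here. The 4 input samples, each a group of its own, had no list here, although per the labels input served as the control. H2Bub1 was precipitated with an antibody, and tagged Fbxl19 and Rnf20 were pulled down with streptavidin beads, per the labels. The OE-low Fbxl19 samples and the Rnf20 sample came from cells that contain BirA, a biotin ligase.

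The submitters' processing notes name BWA 0.5.9-r16, MACS and the mm9 build, with no role for each list. The 5 H2Bub1 lists carry a track line that ends in BCP, the name of a caller of broad domains, and names a combined set with a number and the suffix M, per the file headers. The authors' deposited domain score, in score units whose formula is not given in the sources used here, is above 7 in each line. A further deposited column of the authors holds the domain length in base pairs, and domain ends lie on a 200-bp grid. The 2 Fbxl19 lists have no header, and the caller, its version and its threshold are not given in the sources used here. Their first deposited score resembles a fold enrichment and their second a pileup at the summit, neither of which is stated, and the first was used for ranking. The Rnf20 list has names that begin with MACS and a deposited score from 50 to 3100, from a single library. The other 7 lists are named as combined, and neither peaks per replicate nor read counts were analysed here, and depth per sample is unknown.

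Groups were taken from the sample titles. The description of the OE-high Fbxl19 samples names the H2Bub1 list of the same clone, so the Fbxl19 list of that clone was matched by its name and the sample titles. The description of the third OE-high H2Bub1 sample names no list, so whether it entered the combined list is unknown.

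Positions are given on mm9, counted from 1. The Fbxl19 lists were read as counted from 1, since a peak on the mitochondrial chromosome starts at 1, and the others as counted from 0. A peak was counted as shared if it overlapped the other list by at least 1 bp. The observed share was set against 1000 random placements of the query peaks on the same chromosome, between the first and last position of any list, and against 1000 shifts by 10 to 100 kb in either direction. For each H2Bub1 comparison the 2 lists were merged into regions, which were classed as only in the control list, in both, or only in the treated list. The share of each class with an Fbxl19 or Rnf20 peak was set against 10000 random sets of the same size drawn from the merged regions and matched on length decile. Fbxl19 peaks with and without Rnf20 were compared in the same way with sets matched on score decile. Percentiles describe these lists, since peaks are not replicates. Shares carry exact Clopper-Pearson intervals at 95%, for counting error only. The interval of the difference between states adds the 2 exact intervals in squares. Ends of domains were compared with Fbxl19 summits as listed and with midpoints of Rnf20 peaks, within 1 kb, and the share at both ends again in domains over 2 kb, where 1 peak cannot reach both.

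The regions named in the text were, for each comparison and class, the 3 with the highest score of the authors, taking the lower score of both lists for shared regions and leaving out the mitochondrial chromosome and unplaced contigs. This rule, the comparisons and the first set of alternatives were fixed before the data were examined. The longest region of some classes is named in addition. Alternatives were an overlap of 50% of the query peak, a distance of 1 kb, the top 50% of each list by score, lists of the same size, autosomes only, OE-low in place of OE-high Fbxl19 peaks, and placement of the other list. Added later were local shifts, domains of at least 2 kb, leaving out chromosomes 1, 4, 9, 11 and 14 or chromosome 8, and drawing the sets from control domains alone, matched on length decile or on length decile and 5 score classes.

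The gene table at hand is of another build, GRCm38, so its coordinates were not used, and no mm9 sequence or annotation was used here. Peaks were therefore not assigned to genes, promoters or CpG islands. Calculations used Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1, and figures matplotlib 3.10.9. The overlap code was tested on simulated data: in 2 lists of 5000 peaks with a planted overlap of 40%, it recovered 40%.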

Results

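The series profiled chromatin of mouse J1 embryonic stem (ES) cells, a pluripotent line grown with leukemia inhibitory factor, by chromatin immunoprecipitation and sequencing (ChIP-seq). Fbxl19 is an F-box protein with a CXXC zinc finger, a domain that binds unmethylated CpG. Rnf20 is the E3 ligase that monoubiquitinates histone H2B, and H2Bub1, the modified histone, is known to lie over the bodies of transcribed genes. The series title asks whether Fbxl19 brings Rnf20 to CpG islands and thereby promotes H2Bub1. Of the 21 samples in 12 groups, 4 were Fbxl19 pulldowns: 2 from a clone that expressed tagged Fbxl19 more than 5-fold above the endogenous level (OE-high) and 2 from a clone below that level (OE-low). A single sample was an Rnf20 pulldown. H2Bub1 was profiled in 3 samples of ES cells, 2 of ES cells with Fbxl19 knocked down, 3 of OE-high ES cells, 2 of cells differentiated for 4 days and 2 of differentiated cells with Fbxl19 knocked down. The other 4 samples were input DNA, by title from ES, knockdown, OE and differentiated cells, and no list of theirs was used here. No input was titled for the differentiated knockdown.

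The data were 8 lists of peaks or domains on mm9. Each list but that of Rnf20 is named as combined, and values per replicate were not analysed here, so no spread between replicates was set against a difference and no p-value was computed. Intervals below are exact Clopper-Pearson 95% intervals, which cover counting error in the number of peaks only. Scores are the authors' own values per peak and rank peaks within a list. The track lines of the H2Bub1 lists carry a number with the suffix M, 60 for ES cells, 46 for the knockdown, 46 for OE-high, 36 for differentiated cells and 41 for the differentiated knockdown. The headers do not say what the number counts, and depth per sample is unknown. Fbxl19 levels in the knockdown cells were not analysed here.

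H2Bub1 domains were fewer with Fbxl19 knocked down and more numerous with Fbxl19 overexpressed. The ES list held 2937 domains covering 57.4 Mb. The knockdown list held 1813 domains and 41.9 Mb, 0.617 times the ES number. The OE-high list held 7216 domains and 246 Mb, 2.46 times the ES number and 4.28 times its covered length. Differentiated cells had 5125 domains over 156 Mb, and differentiated knockdown cells had 1090 domains over 15.6 Mb, 0.213 times the number and 0.100 times the length of the differentiated list. Median domain length was 7600 bp in ES cells, 9600 bp in the knockdown, 21600 bp in OE-high, 19800 bp in differentiated cells and 8000 bp in the differentiated knockdown. The order of these numbers did not follow the numbers in the track lines throughout, since OE-high had a smaller number there than ES cells and the differentiated knockdown a larger number than differentiated cells. For the knockdown in ES cells it did follow them, with 46 in the track line against 60 for ES cells and fewer domains. Fbxl19 peaks were short and numbered 13669 in OE-high (median 625 bp) and 2213 in OE-low (median 275 bp), and Rnf20 had 8606 peaks (median 377 bp).

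**Figure D1:**
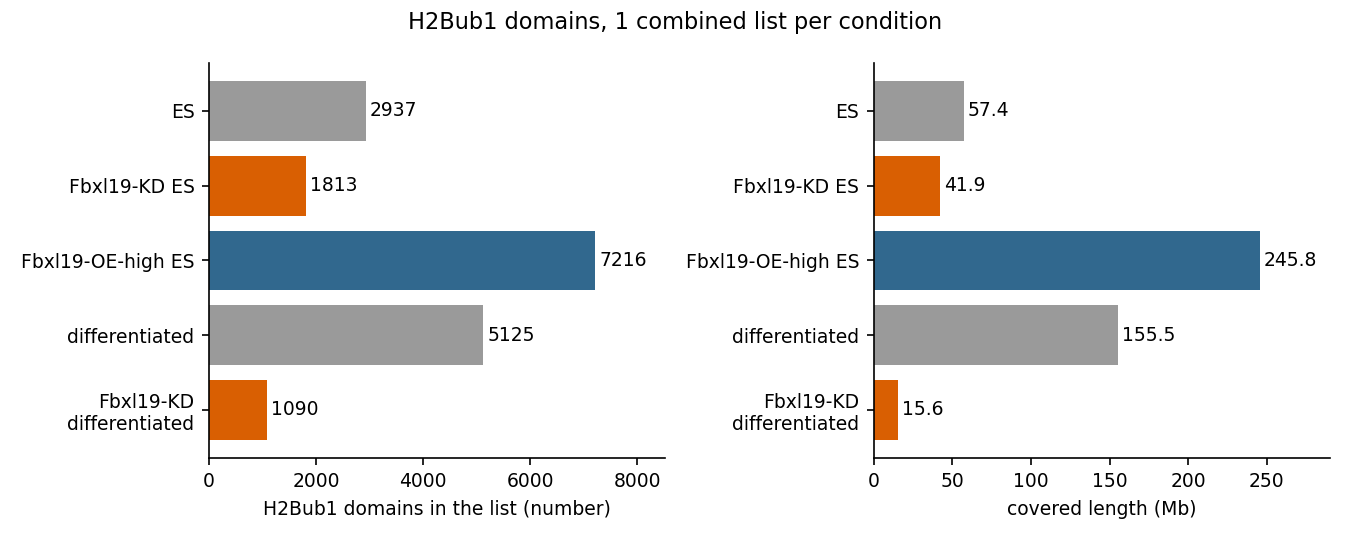
Number of H2Bub1 domains (left) and length covered in Mb (right) in the combined list of each condition, with no error bars because each condition has 1 list. The knockdown lists (orange) hold 1813 and 1090 domains against 2937 and 5125 in their controls (gray), and the OE-high list (blue) holds 7216.

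Most Fbxl19 peaks of the OE-low clone lay at sites also listed in the OE-high clone. Of the 2213 OE-low peaks, 1779 (80.4%, interval 78.7 to 82.0) overlapped an OE-high peak by at least 1 bp. Random placement of the OE-low peaks on their chromosomes gave 0.614% on average, and shifting each by 10 to 100 kb gave 2.46%. In the other direction, 1761 of the 13669 OE-high peaks (12.9%, interval 12.3 to 13.5) met an OE-low peak. Over 4 classes of OE-high peaks by score, that share was 4.12% in the lowest and 30.3% in the highest. None of the 1000 placements or shifts reached the observed share in either direction. With each list limited to the same number of top-scoring peaks, the OE-low share was 37.0% and the OE-high share 36.4%, and with 50% of the OE-high peak to be covered the latter was 6.98%.

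Fbxl19 and Rnf20 peaks coincided far more often than placed peaks did. Of the OE-high Fbxl19 peaks, 3066 (22.4%, interval 21.7 to 23.1) overlapped an Rnf20 peak, 55.7 times the mean of random placements (0.403%) and 19.2 times the mean of local shifts (1.17%). Of the 8606 Rnf20 peaks, 3301 (38.4%, interval 37.3 to 39.4) overlapped an OE-high Fbxl19 peak. The share of Fbxl19 peaks with Rnf20 was 16.6% in the lowest of 4 score classes and 35.0% in the highest, and the share of Rnf20 peaks with Fbxl19 went from 27.6% to 53.3%. OE-low Fbxl19 peaks met Rnf20 in 34.0% of cases (interval 32.1 to 36.0). By chromosome, the share of OE-high Fbxl19 peaks with Rnf20 was 46.5% on chromosome 8 and 8.76% on chromosome 1, around a median of 22.6% over autosomes. The number of Rnf20 peaks per OE-high Fbxl19 peak differed too. Among autosomes it was highest on chromosome 8 (1.27) and lowest on chromosome 1 (0.272), against a median of 0.601. The contrast between chromosomes therefore cannot be told apart from a difference in Rnf20 peak number, which comes from a single library. None of the 1000 placements or shifts came near these genome-wide shares, and asking for 50% of the Fbxl19 peak to be covered gave 13.6%. The fold over random placement was 105 under that rule, 25 within 1 kb and 124 with OE-low peaks, which met 8.81% of Rnf20 peaks. Fbxl19 and Rnf20 were both pulled down with streptavidin, and no list from cells with the biotin ligase alone was used here.

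Fbxl19 and Rnf20 peaks were both enriched in H2Bub1 domains, most of all where they occurred together. In ES cells 2891 of the OE-high Fbxl19 peaks (21.2%, interval 20.5 to 21.8) and 2232 of the Rnf20 peaks (25.9%, interval 25 to 26.9) lay in an H2Bub1 domain. Random placement gave 2.73% and 2.33%, and local shifts gave 7.95% and 8.42%. Among OE-high Fbxl19 peaks with Rnf20, 35.0% (interval 33.3 to 36.7) lay in an ES domain, against 17.1% (interval 16.4 to 17.9) of those without. Sets of Fbxl19 peaks matched on score decile had 22.5%, and the peaks with Rnf20 exceeded all 10000 such sets. The same contrast was 39.2% against 15.8% for OE-low peaks. In the OE-high H2Bub1 list, 70.0% of OE-high Fbxl19 peaks with Rnf20 and 49.2% of those without lay in a domain. Rnf20 peaks there lay in a domain in 67.6% of cases with Fbxl19 and 31.2% without.

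Seen from the domains, 1878 of the 2937 ES domains (63.9%, interval 62.2 to 65.7) held an OE-high Fbxl19 peak and 1140 (38.8%, interval 37.0 to 40.6) an Rnf20 peak, against 19.3% and 10.8% under local shifts. Short and long domains differed. Of the 745 ES domains of at least 20 kb, 85.2% held an OE-high Fbxl19 peak and 56.2% an Rnf20 peak. Of the 111 domains under 1 kb, 8.11% held Fbxl19 and 50.5% held Rnf20, and their median score was 13.5 against 8.72 for the long domains. A short region with a high score, 57391200 to 57391999 on chromosome 16, was in the ES, knockdown ES and OE-high lists. Whether such short domains reflect H2Bub1 or an artifact of the signal or its control was not tested. None of the 1000 placements or shifts reached the observed shares of peaks in ES domains. With only the top 50% of each list by score, the share of Fbxl19 peaks in ES domains was 11.9%. The share of ES domains with a peak depends on list size, being 23.3% for Fbxl19 and 21.8% for Rnf20 with lists of the same size and 14.3% with OE-low Fbxl19 peaks.

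**Figure D2:**
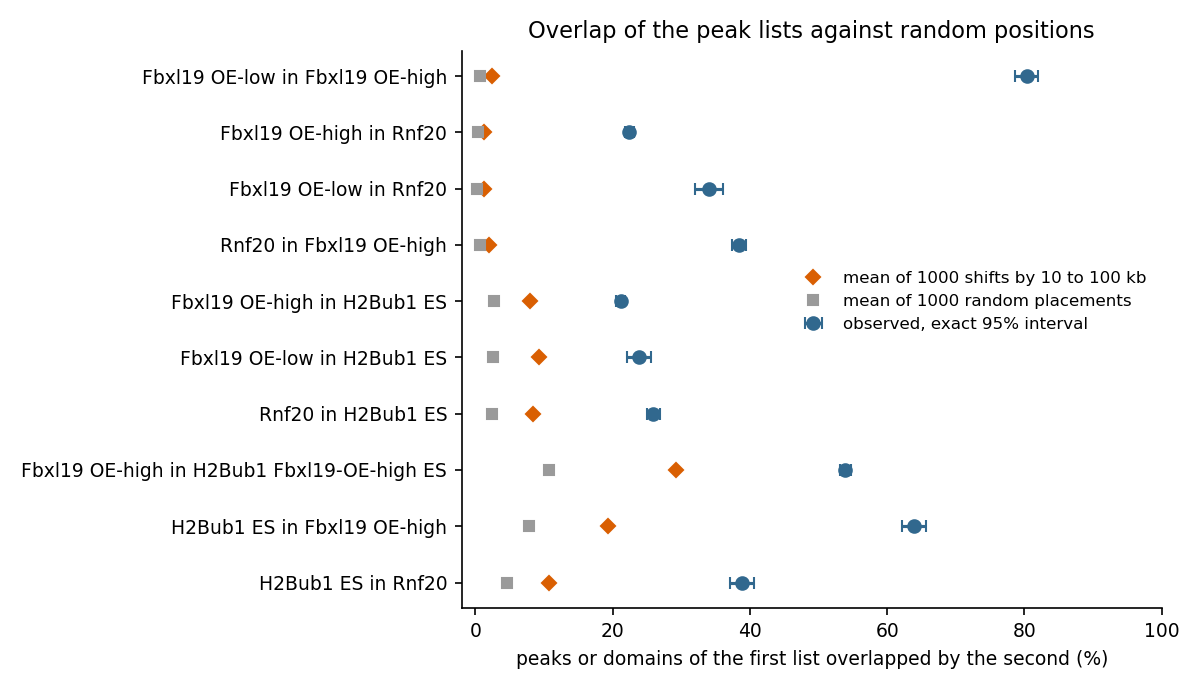
Percent of the peaks or domains of a first list that overlap a second list by at least 1 bp, with exact 95% intervals (circles), the mean of 1000 random placements on the same chromosome (squares) and the mean of 1000 shifts by 10 to 100 kb (diamonds). All 10 observed shares lie above both means, from 21.2% for OE-high Fbxl19 in ES H2Bub1 to 80.4% for OE-low in OE-high Fbxl19.

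Fbxl19 summits were enriched at the ends of H2Bub1 domains, a feature chosen for description after the lists had been seen. An OE-high Fbxl19 summit fell within 1 kb of an end in 1486 ES domains (50.6%, interval 48.8 to 52.4), against 5.24% under local shifts of the summits. These shifts are longer than the median ES domain of 7600 bp, so they do not set ends against the inside of domains. The share was 51.4% in the knockdown list, 48.4% in the OE-high list, 56.9% in differentiated cells and 69.7% in the differentiated knockdown. Midpoints of Rnf20 peaks did so in 28.2% of ES domains, against 2.79% under shifts. Only 78 ES domains (2.66%) had an Fbxl19 summit at both ends, whereas 26.4% had it at the left and 26.8% at the right end, a product of 7.09%. For OE-low summits the share at both ends was 0.511% against a product of 0.208%, and for Rnf20 midpoints 4.80% against 2.72%. In domains over 2 kb, where 1 summit cannot reach both ends, these were 0.234% (interval 0.0860 to 0.509) against 0.220% and 2.58% (interval 2.00 to 3.27) against 2.31%. On chromosome 1 the ES domain from 4797600 to 4823799 began inside an OE-high Fbxl19 peak at 4797267 to 4798370. The ES domain from 4847400 to 4876999 began at an OE-high Fbxl19 peak at 4847448 to 4848476 that overlapped an OE-low and an Rnf20 peak.

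**Figure D3:**
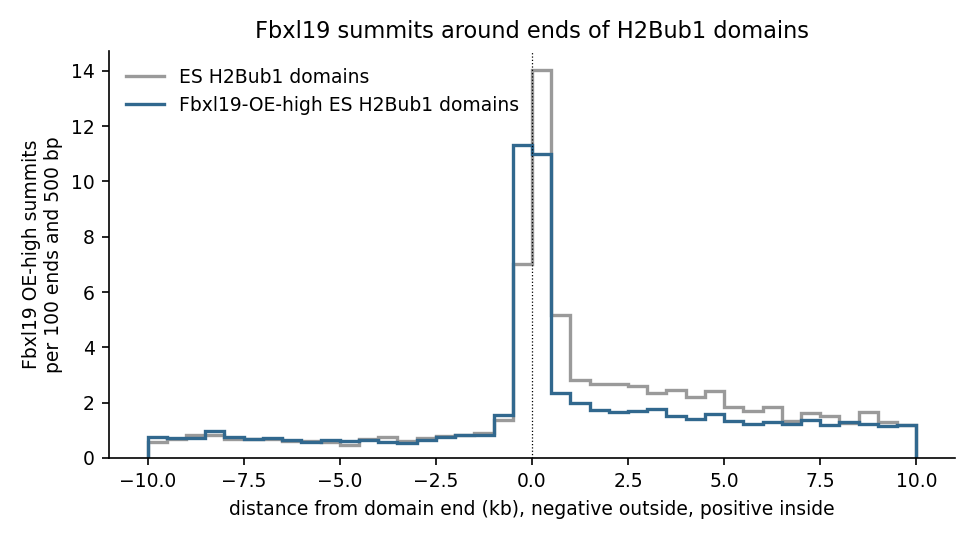
OE-high Fbxl19 summits per 100 domain ends in 500-bp bins, against distance from the end in kb (negative outside, positive inside the domain), for the H2Bub1 domains of ES cells (gray) and of OE-high ES cells (blue). In ES cells the first bin inside holds 14 and the first bin outside 7.01 summits per 100 ends. The bin from 1000 to 1500 bp inside holds 2.83 and the outermost bin outside 0.579.

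**Figure D4:**
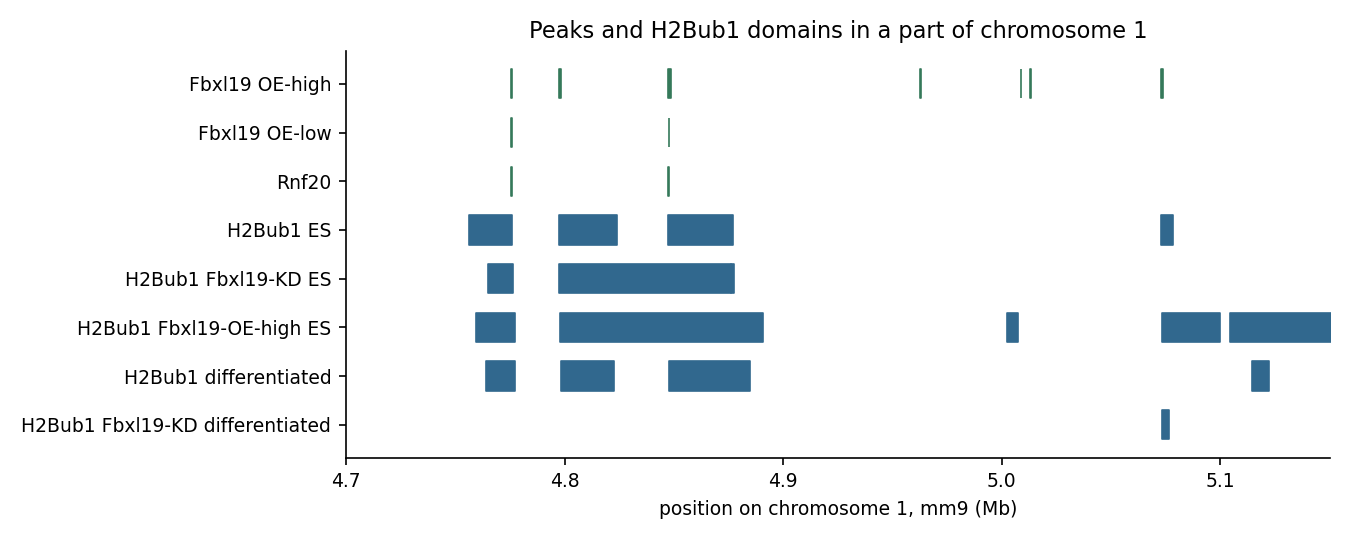
Positions in Mb (mm9) of Fbxl19 and Rnf20 peaks (green) and H2Bub1 domains (blue) of each list on chromosome 1 from 4.70 to 5.15 Mb, an example chosen after the lists had been seen. The ES domains from 4797600 and from 4847400 each begin at an OE-high Fbxl19 peak, and a single domain overlaps both in the knockdown ES list (4797600 to 4875999) and in the OE-high list (4798000 to 4890999).

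Knockdown of Fbxl19 in ES cells, which asks whether H2Bub1 depends on Fbxl19, left about as many H2Bub1 domains in place as were missing. Of the 2937 ES domains, 1532 (52.2%, interval 50.3 to 54.0) overlapped a knockdown domain and 1405 did not. With lists of the same size the kept share was 63.9%. Kept domains were longer (median 10700 bp) than missing ones (5200 bp). Where a region was listed in both, its length was about equal, with a median ratio of 1.00. The knockdown list had 326 domains with no ES counterpart (18.0% of its domains, and 35.4% with lists of the same size). On chromosomes 1 and 11, 71.3% of ES domains were kept (interval 67.9 to 74.5), on chromosomes 4, 9 and 14 36.4% (interval 32.6 to 40.4), and on the other autosomes 49.7% (interval 47.2 to 52.3), sets of chromosomes chosen after the values were seen. Among the last, chromosome 17 kept 69.2%, close to chromosomes 1 (72.2%) and 11 (70.5%).

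Missing regions did not carry Fbxl19 more often than comparable regions. An OE-high Fbxl19 peak lay in 55.3% of the 1405 regions listed only in ES cells (interval 52.7 to 57.9), against 57.4% in random sets matched on length, at percentile 0.355 of 10000 sets. In the 1396 regions listed in both, the share was 77.8% (interval 75.5 to 79.9) against 73.2%, above all sets. Rnf20 gave 32.2% against 36.0% in missing regions and 49.9% against 43.6% in shared regions. Among ES domains alone, matching on score as well as length moved the difference from -3.07 to 0.386 percentage points for Fbxl19 and from -4.32 to -0.212 for Rnf20 in missing domains, and from 2.82 to -0.357 and from 3.96 to 0.199 in kept domains. With lists of the same size, the Fbxl19 difference in missing regions went from -2.14 to 2.79.

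The highest-scoring regions listed only in ES cells lay at 2999800 to 3038399 on chromosome 9 (score 273) and at 98506200 to 98507599 (score 221) and 98502200 to 98504399 (score 130.0) on chromosome 2, none with an Fbxl19 or Rnf20 peak. These scores stood far above the ES list median of 9.21, and the first 2 regions were listed again in both differentiated lists. Whether high-scoring regions, here and in the comparisons below, reflect H2Bub1 or an artifact of the signal or its control was not tested. Among regions in both lists, the highest lower score belonged to 39979800 to 39985999 on chromosome 17, which held an Fbxl19 peak of each clone and an Rnf20 peak. It was followed by 57391200 to 57391999 on chromosome 16 and 108872800 to 108873599 on chromosome 11, each with an Rnf20 peak only. Regions listed only in the knockdown were led by 90771600 to 90772199 on chromosome 18, 95848400 to 95848999 on chromosome 3 and 181747400 to 181748199 on chromosome 2. The longest region listed only in ES cells, picked after its values were seen, ran from 6219200 to 6674199 on chromosome 17 and held 14 OE-high Fbxl19 peaks and 5 Rnf20 peaks.

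In OE-high ES cells nearly all ES domains were present and many more were listed. Of the ES domains, 2628 (89.5%, interval 88.3 to 90.6) overlapped an OE-high domain, and 4706 of the 7216 OE-high domains had no ES counterpart. Shared regions were longer in OE-high cells, with a median of 29200 bp against 10400 bp and a median ratio of 1.75, and 78.2% of them (interval 76.5 to 79.9) were longer in OE-high. The OE-high list also overlapped 94.2% of differentiated domains and 93.2% of knockdown domains. It covers 246 Mb, and the background of these overlaps was high. Local shifts of the domains gave 38.2% for ES, 49.1% for differentiated and 39.9% for knockdown domains. The observed shares lay above all shifts, but a large part of each was also met by shifted domains. New regions had a median length of 18800 bp.

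The new regions carried Fbxl19 often, but less often than shared regions and slightly less than matched sets. An OE-high Fbxl19 peak lay in 62.0% of the 4706 new regions (interval 60.6 to 63.4), against 65.1% in random sets matched on length, below all 10000 sets. Shared regions had 79.5% (interval 77.8 to 81.1) against 71.2%, above all sets. Rnf20 gave 24.7% against 31.5% in new and 47.6% against 35.2% in shared regions. The 309 regions listed only in ES cells were short (median 2200 bp) and had Fbxl19 in 20.4% against 36.2% and Rnf20 in 36.9% against 25.7%. With lists of the same size 58.8% of ES domains met an OE-high domain, and in regions only in ES cells the Rnf20 difference went from 11.2 to -0.884 percentage points, while the Fbxl19 difference went from -15.8 to -1.84 with OE-low peaks and to -2.80 with the top 50% of each list. The differences in shared regions, 8.31 for Fbxl19 and 12.4 for Rnf20 among merged regions, were 2.53 and -0.426 for kept domains among ES domains alone, and 2.01 and -0.568 with these matched on score too. For missing domains among ES domains alone, the Rnf20 difference was 3.62, at percentile 93.8 of sets matched on length. Matched on score too it was 4.83, at percentile 98.7. The Fbxl19 differences there were -21.5 and -17.1.

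By score, the new OE-high regions were led by 80289400 to 80293599 (score 55.3) and 79167200 to 79174999 (score 47.2) on chromosome 10, each with an OE-high Fbxl19 peak and no Rnf20 peak. Next came 3076200 to 3084799 on chromosome 17 (score 41.9), with 2 OE-high Fbxl19 peaks, an OE-low peak and an Rnf20 peak. Regions in both lists were led by 39979600 to 39985999 on chromosome 17, 57391200 to 57391999 on chromosome 16 and 5860200 to 5860999 on chromosome 3. The 3 leading regions listed only in ES cells were those named above on chromosomes 9 and 2. The longest new region, picked after its values were seen, ran from 100428400 to 100801999 on chromosome 12 with 5 OE-high Fbxl19 peaks and 2 Rnf20 peaks.

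**Figure D5:**
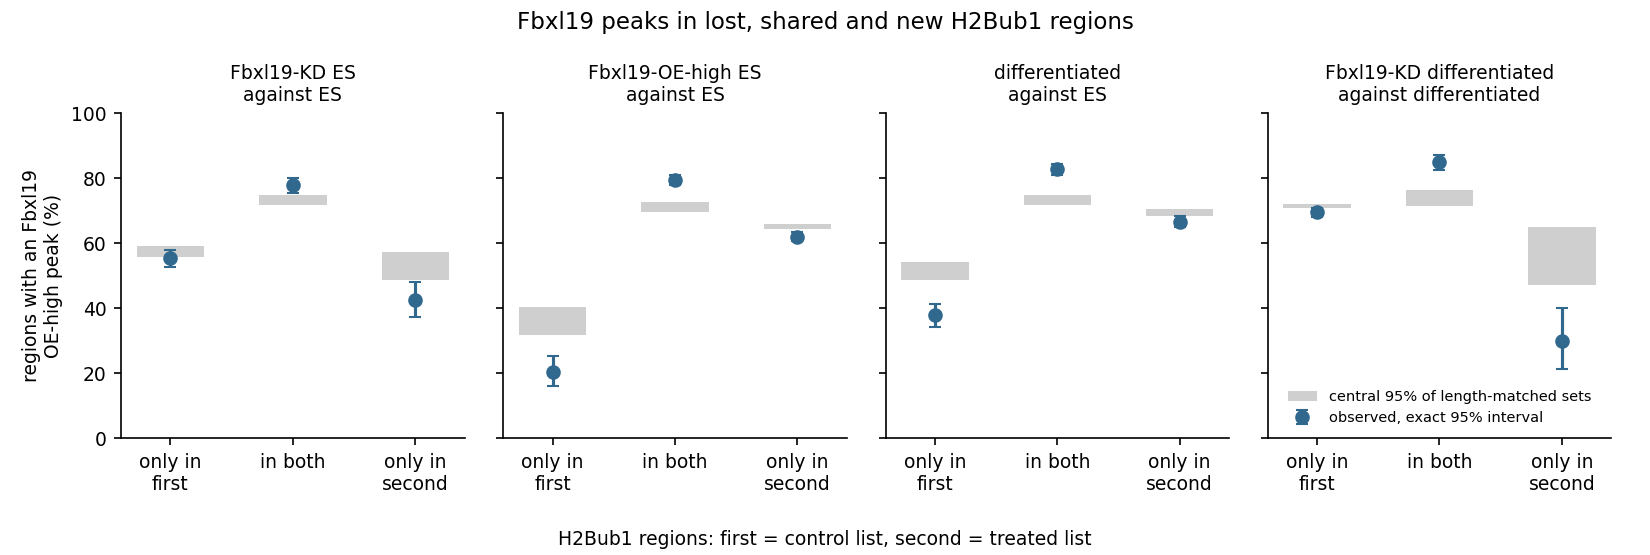
Percent of H2Bub1 regions with an OE-high Fbxl19 peak, with exact 95% intervals, among regions only in the control list, in both lists and only in the treated list, for the 4 comparisons, beside the central 95% of 10000 random sets matched on length (gray boxes). Shared regions lie above their sets in all 4 panels, from 77.8% to 84.9%, and regions only in the treated list lie below them in all 4.

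The list of cells differentiated for 4 days held more H2Bub1 domains than the ES list, and shared regions were longer in it. Of the ES domains, 2199 (74.9%, interval 73.3 to 76.4) overlapped a differentiated domain, and 3006 of the 5125 differentiated domains had no ES counterpart. Shared regions had a median length of 24800 bp in differentiated against 11400 bp in ES cells, with a median ratio of 1.43. Fbxl19 peaks, measured in undifferentiated OE-high cells, lay in 66.6% of the regions only in differentiated cells (interval 64.8 to 68.3) against 69.3% in matched sets, and in 82.7% of shared regions (interval 81.0 to 84.4) against 73.4%. Regions only in ES cells, with a median of 4000 bp, had Fbxl19 in 37.8% against 51.5% and Rnf20 in 37.9% against 30.8%. These differences lay outside all 10000 matched sets. The differences in shared regions, 9.34 percentage points for Fbxl19 and 10 for Rnf20 among merged regions, were 5.01 and -0.866 for kept domains among ES domains alone, and 4.20 and -1.41 with these matched on score too. In regions only in ES cells the Fbxl19 difference of -13.7 was -0.445 with OE-low peaks and -0.282 with the top 50% of each list, and the Rnf20 difference of 7.18 was 2.56 with lists of the same size. For missing domains among ES domains alone, the Rnf20 difference was 2.58, at percentile 96.5 of sets matched on length. Matched on score too it was 4.21, at percentile 99.9. The Fbxl19 differences there were -14.9 and -12.5.

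Regions only in ES cells were led by 108872800 to 108873599 on chromosome 11, 123370800 to 123371399 on chromosome 9 and 15519600 to 15520199 on chromosome 8, each with an Rnf20 peak and no Fbxl19 peak. Those only in differentiated cells were led by 77578000 to 77578399 on chromosome 13, 3079200 to 3084799 on chromosome 17 and 79224000 to 79229599 on chromosome 10, and the latter pair held 2 and 1 OE-high Fbxl19 peaks. The regions shared at the highest scores were 2999800 to 3038399 on chromosome 9, 98506000 to 98507599 on chromosome 2 and 39979800 to 39985999 on chromosome 17. The longest region only in differentiated cells, picked after its values were seen, ran from 34934600 to 35320399 on chromosome 11 with 4 OE-high Fbxl19 peaks.

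In differentiated cells the knockdown left few H2Bub1 domains. Of the 5125 differentiated domains, 968 (18.9%, interval 17.8 to 20) overlapped a domain of the differentiated knockdown, and 4157 did not. Shared regions were shorter in the knockdown, with a median of 9000 bp against 26400 bp and a median ratio of 0.478, and 92.6% of the 962 shared regions were shorter. In the knockdown list 100 domains (9.17%), with a median length of 1600 bp, had no differentiated counterpart, a share of 51.1% with lists of the same size and 27.7% with the top 50% of each list. On chromosomes 1 and 11, 31.3% of differentiated domains were kept (interval 28.3 to 34.3), on chromosomes 4, 9 and 14 16.9% (interval 14.4 to 19.6), and on the other autosomes 16.1% (interval 14.9 to 17.4).

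Regions kept in the differentiated knockdown carried Fbxl19 and Rnf20 more often than those missing. An OE-high Fbxl19 peak lay in 84.9% of the 962 shared regions (interval 82.5 to 87.1) against 73.9% in matched sets, and in 69.5% of the 4157 missing regions (interval 68.1 to 70.9) against 71.5%. For Rnf20 the shares were 47.9% against 33.9% and 28.6% against 32.2%. The shared values lay above and the missing values below all 10000 sets. With 50% of the domain to be covered, 9.07% of differentiated domains were kept, and with lists of the same size 47.8%, where the differences in shared regions were 3.88 in place of 11 percentage points for Fbxl19 and 6.54 in place of 14 for Rnf20. The Fbxl19 difference in shared regions was 6.56 with the top 50% of each list, and among differentiated domains alone, matched on length and score, the differences were 7.20 for Fbxl19 and 9.58 for Rnf20 in kept and -1.68 and -2.23 in missing domains. For the 100 new regions, the Fbxl19 difference from matched sets went from -25.7 percentage points with OE-high peaks to 1.03 with OE-low peaks, and the Rnf20 difference from 15.7 to -1.07 with lists of the same size.

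Missing regions were led by 77578000 to 77578399 on chromosome 13, 3079200 to 3084799 on chromosome 17 and 5328600 to 5344799 on chromosome 11. Shared regions were led by the 3 named for differentiation on chromosomes 9, 2 and 17, and regions only in the knockdown by 56071400 to 56071799 on chromosome 9, 108873000 to 108873599 on chromosome 11 and 123370800 to 123371399 on chromosome 9, each with an Rnf20 peak and no Fbxl19 peak. The longest missing region, picked after its values were seen, ran from 12386200 to 12796799 on chromosome 14 with an OE-high Fbxl19 peak and an Rnf20 peak.

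Fewer control domains were kept under knockdown in differentiated than in ES cells. The kept share was 52.2% in ES cells and 18.9% in differentiated cells, a difference of 33.3 percentage points (interval 31.1 to 35.4, counting error only). The difference between states was not tested against replicates, since each state had 1 list with and 1 list without the knockdown. With lists of the same size within each state it was 16.1 percentage points. The kept share depends on list size, as the knockdown lists held 0.617 (ES) and 0.213 (differentiated) times the domains of their controls. In the other direction the order was reversed. A control domain was overlapped by 82.0% of the knockdown ES domains and by 90.8% of the differentiated knockdown domains.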

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

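Leaving out domains under 2 kb, leaving out chromosomes, local shifts, drawing sets from control domains alone, matching on score and all alternatives for the number of domains were chosen after seeing the data. No paired analysis was possible because the lists compared are named as combined, or hold a single library for Rnf20, so that values per replicate were not analysed here and the comparisons come from no test. For the same reason leaving out replicates could not be run. CpG islands and promoters, and gene lists, were not run, nor were their alternatives, since no mm9 sequence or annotation was used here. Values follow as percent of query peaks, or of control domains kept. The numbers of domains in the 4 comparisons stayed within 1.5 times and on the same side of 1 in all 12 alternative values. Of 336 combinations of a named region and a setting, 46 no longer listed the region, and of the other 290 the region kept its class in 284. Of 119 alternative shares, 77 lay outside the interval of the reported value, of 36 folds over random placement 26 did, and of 212 differences from matched sets 64 moved and 10 reversed. For these, the cause was not tested.

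With 50% of the query covered, the values were 13.6% for Fbxl19 with Rnf20, 19.1% for Fbxl19 in ES H2Bub1, 24.5% for Rnf20 in ES H2Bub1, and 48.0%, 86.7%, 71.3% and 9.07% of control domains kept in knockdown ES, OE-high, differentiated and differentiated knockdown cells, with 38.9 points between the knockdown states. Within 1 kb, Fbxl19 with Rnf20 was 24.9%, Fbxl19 in H2Bub1 22.0% and Rnf20 in H2Bub1 27.5%. With the top 50% of each list by score, OE-low in OE-high Fbxl19 was 74.1%, Fbxl19 with Rnf20 19.3%, Fbxl19 in H2Bub1 11.9%, Rnf20 in H2Bub1 22.7%, and domains kept 48.1%, 70.8%, 55.7% and 15.3% in the order above. With lists of the same size the values were 37.0%, 25.9%, 27.3% and 37.7% for the overlaps, 63.9%, 58.8%, 54.7% and 47.8% for domains kept, and 16.1 points between the knockdown states. OE-low Fbxl19 peaks gave 34.0% with Rnf20 and 23.8% in H2Bub1. With domains of at least 2 kb, Rnf20 in H2Bub1 was 24.7%, and domains kept were 54.1% in knockdown ES, 93.1% in OE-high and 78.4% in differentiated cells. Without chromosomes 1, 4, 9, 11 and 14, Fbxl19 in H2Bub1 was 17.6%, Rnf20 in H2Bub1 22.9%, and domains kept 49.2%, 87.4%, 70.9% and 16%. Without chromosome 8, Fbxl19 with Rnf20 was 21.1%.

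Differences from matched sets, in percentage points, changed sign in 10 cases. With lists of the same size, Fbxl19 in regions missing from knockdown ES cells became 2.79, Rnf20 in regions missing from OE-high -0.884 and Rnf20 in regions new in the differentiated knockdown -1.07. With OE-low peaks, Fbxl19 in regions new in the differentiated knockdown became 1.03. With sets from control domains alone, matched on length, Rnf20 became -0.426 in domains kept in OE-high and -0.866 in domains kept in differentiated cells. With these matched on length and score, Fbxl19 became 0.386 in domains missing from and -0.357 in domains kept in knockdown ES cells, and Rnf20 became -0.568 in domains kept in OE-high and -1.41 in domains kept in differentiated cells.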

Other observations

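The tests on domain ends moving between lists and on domain length by chromosome were set before their results were seen, and all other tests and comparisons given here were chosen afterwards. Differentiated H2Bub1 domains without an ES counterpart were present in the differentiated knockdown less often than those also in ES cells. Of the 3006 without one, 7.15% (interval 6.26 to 8.13) overlapped a domain of the differentiated knockdown, against 18.4% in sets matched on length and 14.2% in sets matched on length and score. Of the 2119 that were also in ES cells, 35.5% (interval 33.5 to 37.6) did, against 19.6% and 25.5%. Of the domains without an ES counterpart, 91.2% (interval 90.1 to 92.2) were listed in undifferentiated OE-high cells, below the 93.8% of sets matched on length and the 98.4% of domains also in ES cells. The same order held for the knockdown ES list (6.22% against 60.6%). It also held for OE-high Fbxl19 peaks (66.6% against 80.5%) and Rnf20 peaks (25.1% against 41.9%). The contrast was therefore not particular to the differentiated knockdown, and whether it reflects dependence on Fbxl19 was not tested.

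A group of 596 ES domains (20.3%, interval 18.9 to 21.8) was listed in all 4 other H2Bub1 lists, with a median length of 14700 bp, an OE-high Fbxl19 peak in 81.7% and an Rnf20 peak in 48.7%. Another 201 ES domains (6.84%, interval 5.96 to 7.82) were in none of the others, with a median length of 2400 bp, Fbxl19 in 15.9% and Rnf20 in 37.3%. The region from 2999800 to 3038399 on chromosome 9, the top region only in ES cells against knockdown and OE-high ES cells, was listed in differentiated cells (score 226) and in the differentiated knockdown (score 208). On chromosome X the Rnf20 list held 271 peaks and the OE-high Fbxl19 list 52, or 5.21 Rnf20 peaks per Fbxl19 peak, against a median of 0.601 over autosomes.

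More of the OE-high H2Bub1 domains were also in the knockdown ES list on chromosomes 1 and 11 (47.8%) than on the other autosomes (18.8%), among which chromosome 17 had 32.8% there and 10% in the differentiated knockdown list. In the ES list chromosomes 4, 9 and 14 were raised as well (45.2%, 42.1% and 42.2% against a median of 30.1%), while in the knockdown ES list they had 20.8%, 17.8% and 12.6% against a median of 18.6%. A few local clusters on chromosomes 1 and 11 are argued against, since all 16 windows of 20 Mb there lay above the median of the other windows, as are longer domains, since the share lay at percentile 100 of sets matched on length. Extra copies of chromosomes 1 and 11 in the cells may account for it, as in the differentiated knockdown list again 16 of 16 windows lay above the median, but chromosomes 4, 9 and 14 would need copies in some of the cells only. Input was the control per the labels. By sample title, ES, knockdown, OE and differentiated cells each had an input, and the differentiated knockdown had none of its own. Which input served which list, and whether it came from the same clone, is not known. A copy number difference therefore stays open, and no biological explanation was tested.

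The H2Bub1 lists differed in number of domains, lowest with the knockdown and highest in OE-high among ES cells, and read number is argued against for OE-high against ES cells (-14 M in the track lines, with more domains) and for the differentiated knockdown against its control (5 M more, with fewer domains), if that number counts reads. For knockdown against ES cells it stays open (-14 M, with fewer domains). Weaker signal over background in the knockdown lists stays open too: among domains of at least 2 kb, the highest of 4 score classes was kept more often than the lowest by 50.9 percentage points in ES and 38.2 in differentiated cells, which a true lowering of H2Bub1 over all domains would also give. A second list without any change could give it as well, since listed scores lie above 7 and low-scoring domains lie near that limit. These values therefore cannot decide. Whether stronger signal over background gave the more numerous and longer domains of the OE-high and differentiated lists was not tested. Loss of whole domains aimed at those with an OE-high Fbxl19 peak is argued against in differentiated cells. Missing domains there carried Fbxl19 at percentile 0 of sets matched on length and score. In ES cells such loss cannot be told apart from chance, at percentile 70.7. The test cannot decide on shortening, since 1 bp of overlap counted as kept and 92.6% of shared differentiated regions were shorter in the knockdown. Its Fbxl19 peaks came from undifferentiated OE-high cells, so sites in differentiated cells are unknown. Dependence of H2Bub1 on Fbxl19, as the design names it, stays open, and whether a lowering is restricted to Fbxl19 sites was not settled in either state.

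Fbxl19 summits were enriched at the ends of H2Bub1 domains, and 0 of 1000 local shifts gave as many ES domains with a summit at an end. This argues against peak density at the distance of the shifts as the cause. The shifts are longer than the median ES domain, so they cannot decide on many peaks inside or next to domains. Summits per 100 ES ends were 14 in the first 500 bp inside and 2.83 from 1000 to 1500 bp inside. Outside, they were 7.01 and 0.885 at the same distances. Whether domains start at an Fbxl19 peak and end elsewhere stays open: the share with an OE-high summit at both ends was -4.43 percentage points from the product of the single shares (-5.91 in domains over 2 kb), but OE-low summits lay at both ends in 0.511% against a product of 0.208% (0.234% against 0.220% in domains over 2 kb). The latter OE-low share rests on 6 domains and cannot decide. With OE-high summits the difference in domains over 2 kb was negative in all 5 H2Bub1 lists, from -4.27 to -12.2. In the 1939 domains matched 1 to 1 between the ES and OE-high lists, leaving out merged, split and missing ones, ends with an Fbxl19 peak moved less, by a median of 200 bp against 3800 bp, a difference of -3600 bp that lay below all 10000 relabelings of the ends. In the 1116 of these with a summit at 1 end, that end moved less than the other in 85.9% of untied cases (interval 83.6 to 87.9). Sharp signal at such ends could give the same, and this was not tested.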
